A study of Mus musculus with 12 samples.

How the data were processed

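Mice carried B16-F10 tumours, a transplantable mouse melanoma line, in the skin. Tumour leukocytes were taken from 4 treatments: vehicle (PBS) with control IgG, PBS with immune checkpoint blockade (ICB), cyclophosphamide (CTX) with IgG, and CTX with ICB. Cyclophosphamide is an alkylating chemotherapy drug and was given at 250 mg per kg. ICB was a pair of blocking antibodies, 200 µg against PD-1 and 100 µg against CTLA-4, started on day 8 and repeated until the end of the experiment; tumours were harvested 14 days after CTX. Live CD45+ cells were sorted after a Percoll gradient and captured on the 10x 5′ platform with oligonucleotide-labelled antibodies (CITE-seq). Each treatment has 1 RNA library, 1 antibody library (ADT) and 1 T cell receptor library, 12 samples in all. No file is listed for the 4 receptor libraries, so receptor sequences are not analysed here.

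Per the labels, the authors aligned reads to GRCm38 and counted with Cell Ranger 6.1.1. The deposited RNA files hold raw UMI counts of 32285 genes per cell barcode, and the deposited antibody files hold raw counts of 143 features per barcode. Whole-number values were checked in every file. The antibody panel holds 138 antibodies, among them 3 isotype controls, and 5 hashtag antibodies. The labels do not say what each hashtag marks, so a hashtag pool is described and never used as a replicate.

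Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, 21281 of 21457. The doublet caller Scrublet (in scanpy 1.11.5, expected rate 0.06) marked 4 cells, 0.019% of those kept, and therefore did not work on these libraries. Barcodes with 2 or more hashtags were removed as multiplets, 1882 in all, as was 1 further cell marked by Scrublet, and 19398 cells were analysed. A hashtag was called on a barcode with at least 50 counts of it that made up at least 10% of the barcode's hashtag counts. From the observed multiplets, pairs of cells of the same pool were expected among 11.0% of the tagged cells of PBS+IgG, 3.70% of PBS+ICB, 11.9% of CTX+IgG and 2.50% of CTX+ICB; these, and all doublets among untagged cells, remained.

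The 4 libraries were clustered together (2000 variable genes without antigen receptor, mitochondrial and ribosomal protein genes, 30 principal components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2, seed 1), which gave 27 clusters. A cluster was named only from marker lists fixed before the data were examined, with at least 3 markers found in at least 25% of its cells (for classes other than T cells also at least 2-fold over the other cells). T cell clusters were divided by the share of their cells with Cd3 (80%), Foxp3 (50%), Trdc (50%), Cd8a or Cd8b1 (75%, or under 25%) and Cd4 (30%) UMIs. These thresholds were set after the data had been seen, and the T cell clusters they leave without a subset are reported as such. A cluster was also left unnamed if the median of its cells' UMIs, each over the median of its library, was under 1/3 and none of its markers was among its 10 top genes; cluster 24, with Cd3 UMIs in 96.7% of its cells, was left out this way. No library integration was applied. A cluster that comes mostly from 1 library may be that library rather than a cell type. Over 50% of the cells came from 1 library in clusters 1, 6, 12, 13, 17, 18, 19, 20 and 23 (CTX+IgG), 4, 22 and 24 (PBS+ICB) and 0 and 26 (CTX+ICB), for example 12 of 12 macrophages in cluster 26, 253 of 352 neutrophils in cluster 17 and 631 of 964 monocytes and macrophages in cluster 6.

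UMIs were summed per library and class (numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, Python 3.11.15). Values are CPM, the UMIs of a gene scaled to a common class sum, and comparisons are log2 ratios of CPM for genes with at least 50 UMIs over both libraries, in classes with at least 50 cells in each. Gene symbols are those of the deposited feature files. There is 1 library per treatment, so there were no replicates, no test was run and no p-value is given. Intervals are exact 95% intervals (Clopper-Pearson for shares, conditional Poisson for ratios of counts); they cover counting error only. A gene without UMIs in 1 library is given as a bound against 3 counts. "Higher" and "lower" describe libraries.

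Gene lists were fixed before the data were examined: cytotoxic effector, terminal effector, exhaustion and inhibitory receptors, naive and memory T, cell cycle, type I interferon, interferon-gamma, MHC class I and class II, suppressive macrophage, inflammatory myeloid, Treg activation, T helper, p53 target, glycolysis and hypoxia, immediate early and stress, granulocyte progenitor and B16 melanoma genes. Each list is summarised by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of equal size matched on expression. Percentiles describe these libraries, not the treatments.

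Named genes follow a rule fixed before the data were examined. For CD8 T cells and for the largest myeloid class, they are the 8 highest and 8 lowest log2 ratios among genes with at least 200 UMIs over both libraries and 50 in the higher one, whose hashtag pools do not overlap where each library has at least 3 pools of 20 cells. PBS+IgG has fewer pools than that for CD8 T cells, so the pool condition was not applied there. Where it was applied, pools did not overlap for 1.74 to 15.3% of all compared genes, against 0.794 to 2.86% by chance. Antigen receptor, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and numbered gene models were left out. The rule also names up to 4 members of each list with the largest ratios, and Pdcd1, Ctla4, Cd274, Gzmb, Ifng, Mki67, Tcf7, Tox and Foxp3. Antibodies were compared as CPM of non-hashtag antibody counts in cells with both barcodes, for antibodies with at least 500 counts; the 4 highest and 4 lowest, PD-1 (CD279) and CTLA-4 (CD152) are named by rule. Not every gene and antibody that the rules name is printed.

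Alternatives tried were a stricter filter (500 genes, 5% mitochondrial), only cells with an antibody barcode, no doublet removal, Leiden resolution 0.5 and 2, a per-cell CD8 gate (a Cd3 UMI, a Cd8 UMI and no Cd4 UMI), gene minimums of 20 and 200 UMIs, TMM scaling (edgeR 4.0.16, R 4.3.3), each hashtag pool left out in turn, and isotype scaling and mean centred log-ratios (CLR) for antibodies. Leaving out a pool removed only the cells tagged with it, and untagged cells of that pool stayed. Removing the highest Scrublet scores (above the 90th percentile), removing cells with at least 3 markers of another class, and removing neutrophils with Elane or Mpo UMIs for the progenitor list, were chosen after seeing the data. The other classes were macrophage, neutrophil or B for CD8 T cells, and CD8 T or NK for monocytes and macrophages. NK markers in CD8 T cells, and neutrophil markers in monocytes and macrophages, were not used for removal. On simulated counts shaped like a CD8 comparison (9998 genes), the intervals covered the true ratio for 95.5% of genes, and 96.0% of genes set apart 2-fold had an interval on the right side of 0. These counts were drawn with Poisson error, which the intervals assume, so coverage near 95% was given in advance. The simulation checks the calculation only. It has no spread between cells or pools, which the real counts have. Where TMM moves the median of all genes by over 0.1, that shift was 0.22 in CD8 T cells for CTX+IgG and 0.14 for CTX+ICB against PBS+IgG. It was 0.14 in monocytes and macrophages for CTX+IgG against PBS+IgG, and in NK cells 0.25 and 0.12 for CTX+IgG and CTX+ICB against PBS+IgG and -0.10 between the CTX libraries. In CD4 T cells it was 0.19 and 0.17 for CTX+IgG and CTX+ICB against PBS+IgG and 0.14 for CTX+ICB against PBS+ICB, and in Treg 0.14 for CTX+IgG against PBS+IgG. The shifts were largest in neutrophils, from -0.79 to -0.35 in the comparisons other than the one between the CTX libraries.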

Results

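CD45+ cells of B16-F10 tumours were profiled in 4 RNA libraries, 1 per treatment, with a paired antibody library each. The RNA files held 2582 barcodes in PBS+IgG, 6742 in PBS+ICB, 7498 in CTX+IgG and 4635 in CTX+ICB, where the labels state that 1700 to 6400 cells were prepared per library. Total UMIs were 16198665, 47875388, 42955694 and 28670659 in that order, with medians of 3728.5, 5217.5, 3994 and 4465 UMIs per barcode. After filtering and removal of multiplets, 2220, 6007, 6794 and 4377 cells were analysed. The antibody files held 5506743, 15225286, 12733777 and 10694573 counts, and their barcodes covered 37.7%, 74.95%, 35.8% and 69.1% of the RNA barcodes. Covered barcodes were deeper than the others in each library, with medians of 8168 against 2812 UMIs in PBS+IgG and 6683 against 3164 in CTX+IgG. Values of antibodies and hashtag pools therefore describe the deeper cells. The 5 hashtags divided each library into pools of 25 to 264 cells in PBS+IgG, 635 to 1218 in PBS+ICB, 31 to 939 in CTX+IgG and 168 to 1067 in CTX+ICB.

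Lymphoid and myeloid classes took very different shares of the 4 libraries. CD8 T cells made up 10.4% of PBS+IgG (95% interval 9.12 to 11.7%), 33.2% of PBS+ICB (32.0 to 34.4%), 21.4% of CTX+IgG (20.4 to 22.4%) and 60.3% of CTX+ICB (58.8 to 61.7%). Neutrophils, the short-lived granulocytes of acute inflammation, took 29.8%, 12.9%, 4.09% and 1.14% in the same order. Monocytes and macrophages took 18.6%, 14.8%, 27.1% and 6.99%, and NK cells, the innate cytotoxic lymphocytes, 6.71%, 11.1%, 21.0% and 8.43%. CD4 T cells took 3.56%, 10.4%, 2.64% and 11.4%, and Foxp3+ regulatory T cells (Treg) 6.13%, 2.45%, 5.26% and 2.74%. The sort for live CD45+ cells and the Percoll gradient can set these shares. T cells left without a subset, in clusters 8 (Dapl1, Tcf7, Lef1), 22 (Cx3cr1, Klrg1) and 25 (Il2, Il21), made up 8.11%, 6.08%, 4.37% and 2.97%, and cells left unnamed, in clusters 10 (Cd300e, Ace, Treml4) and 24 (shallow cells, 91.7% with a Cd8 UMI), 3.29%, 3.35%, 4.37% and 3.43%. Shares differed among the cells with an antibody barcode, at 19.5%, 41.0%, 28.7% and 66.1% for CD8 T cells, 7.19%, 9.20%, 2.25% and 0.948% for neutrophils and 32.4%, 17.9%, 37.1% and 8.36% for monocytes and macrophages. There NK cells had 4.25%, 7.01%, 5.65% and 4.57%, CD4 T cells 2.20%, 10.1%, 1.15% and 9.75%, Treg 14.8%, 3.09%, 10.6% and 3.66%, and B cells 2.93%, 1.245%, 0.1% and 0.305%, against 6.71%, 2.60%, 0.618% and 0.525% of all cells.

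**Figure D1:**
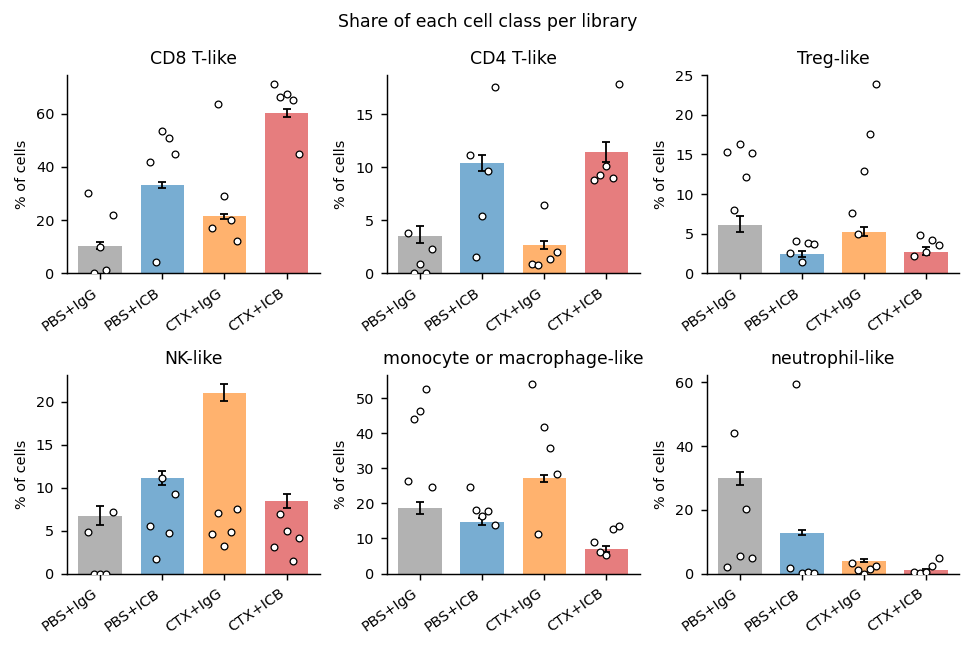
Share of analysed cells (%, vertical axis) in each cell class for the 4 libraries; bars give the library value, error bars the exact 95% interval for counting error and points the hashtag pools. CD8 T cells ranged from 10.4% in PBS+IgG to 60.3% in CTX+ICB, while neutrophils ranged from 29.8% to 1.14%.

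The first comparison, PBS+ICB against PBS+IgG, asks how the tumour leukocytes differ with checkpoint blockade alone. The CD8 T cell share was 3.202-fold higher (log2 ratio 1.68, 1.48 to 1.88), and CD8 T cells carried more RNA of interferon-induced genes, of granzyme A and of immediate early genes. Monocytes and macrophages carried more of the interferon-gamma-induced chemokines Cxcl9 and Cxcl10. They carried less of the genes linked to tissue-remodelling macrophages, such as Folr2, Mmp12 and Apoe. CD4 T cells were also more frequent (log2 ratio 1.55) and Treg, which restrain other T cells, less frequent (-1.32). The neutrophil share was lower (-1.21), NK cells stood at 0.72 and monocytes and macrophages at -0.33.

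In CD8 T cells, whose largest cluster was cluster 3 in both libraries (37.4% of PBS+IgG and 36.9% of PBS+ICB), all 16 measured type I interferon genes were higher, with a median log2 ratio of 1.25 (percentile 100). These genes encode antiviral effectors, and Rsad2 (1.67), Isg15 (1.67), Zbp1 (1.57) and Usp18 (1.52) had the largest ratios. Of 18 interferon-gamma genes, 16 were higher and 2 lower (median 0.58, percentile 100), among them the GTPase genes Iigp1 (1.68) and Irgm1 (1.11). All 10 genes of MHC class I presentation were higher (median 0.47, percentile 100.0), such as Tapbp (0.69) and H2-K1 (0.65). Cytotoxic effector genes divided into 11 higher and 8 lower (median 0.15, percentile 99.5): granzyme A (Gzma) was at 2.94 (148 against 19.3 CPM), whereas the granzyme genes Gzme (-2.62), Gzmd (-2.32) and Gzmf (-2.22) were lower. These lower granzyme genes lead the top genes of CD8 cluster 21. It held 19 CD8 T cells of PBS+IgG (8.26%) and 33 of PBS+ICB (1.66%). Gzme moved to -2.004 without PBS+IgG pool 5 and to -3.23 without PBS+ICB pool 1. The exhaustion list had 9 members higher and 8 lower (median 0.20, percentile 99.7), with Ctla4 at 0.86, Cd38 at 0.78, Nr4a2 at 0.73 and Ccrl2 at -0.53. Pdcd1, the gene of PD-1, did not differ beyond counting error (-0.02, -0.11 to 0.07), and Tox was at -0.27. Genes of naive and memory T cells had 4 members higher and 9 lower (median -0.41, percentile 0.06; -1.05 under the per-cell gate), among them Id3 (-2.41) and the chemokine receptor gene Ccr7 (-1.59), while Tcf7 was at -0.41. Cell cycle genes had 2 higher and 18 lower (median -0.25, percentile 0), for example Ccnb2 (-0.53) and Stmn1 (-0.51), with Mki67 at 0.03. Among terminal effector genes 4 were higher and 4 lower (median 0.15, percentile 89.4), with the fractalkine receptor Cx3cr1 at -1.47 and Prdm1 at 0.85.

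All 15 immediate early and stress genes were higher in CD8 T cells (median 1.22, percentile 100), with Fos at 2.54, Fosb at 2.51, Egr1 at 1.70 and Hspa1a at 1.63. Such genes also respond to tissue dissociation. Among p53 targets 4 were higher and 10 lower (median -0.19, percentile 4.32, with Bbc3 -1.31), and among glycolysis genes 8 were higher and 8 lower (median 0.00, percentile 58.9), with Eno1 at -1.53 and Gapdh at -1.06. MHC class II genes, which mouse T cells lack and antigen-presenting cells carry, had 1 higher and 5 lower (median -1.46, percentile 0), with Cd74 at -1.79 and H2-Ab1 at -1.76. This list turned to 0.06 under the per-cell CD8 gate and was at -2.55 once cells with markers of another class were removed, a setting chosen after seeing the data. It was at -2.105 under the stricter filter and at -0.49 without PBS+IgG pool 5. Genes named by size on the higher side were Ifitm1 (7.98, 5.50 to 13.28, 1 UMI in PBS+IgG), the cytokine gene Csf2 (3.01), Psme2b (2.73), the chemokine receptor gene Ccr2 (2.22) and Tent5c (2.02). On the lower side were Igfbp7 (-2.66), Cd9 (-2.12), Serpinb9b (-2.12), Slc16a11 (-1.996) and the neutrophil-attracting chemokine gene Cxcl2 (-4.15). In neutrophils Cxcl2 was at 57171 CPM in PBS+IgG and 34035 in PBS+ICB, against 110.1 and 6.20 CPM in CD8 T cells. The gene turned to 0.41 without PBS+IgG pool 5 and was at -5.25 without PBS+ICB pool 4. Serpinb9b moved to -1.50 without PBS+IgG pool 5 and Psme2b to 3.37 without PBS+IgG pool 1. Ifng was at 1.35, Gzmb at 0.97 and Cd274, the PD-L1 gene, at 1.03.

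In monocytes and macrophages, cluster 2 held most cells of both libraries (51.3% of PBS+IgG and 65.9% of PBS+ICB), and the macrophage cluster 13 held 36.6% and 11.3%. All 19 interferon-gamma genes were higher (median 1.70, percentile 100), with Cxcl10 at 3.198 (1277 against 139 CPM), Socs1 at 3.14, Iigp1 at 2.82 and Cxcl9 at 2.65; Iigp1 moved to 1.76 without PBS+ICB pool 1. All 17 type I interferon genes (median 1.06, percentile 100; Ifi44 1.74, Cmpk2 1.58) and all 10 MHC class I genes (median 1.03, percentile 100, with Nlrc5 1.38, Tap1 1.33) were higher. For MHC class II, 7 of 8 genes were higher (median 0.17, percentile 86.2), led by the transactivator gene Ciita (1.44). All 15 suppressive macrophage genes were lower (median -1.17, percentile 0; -1.81 without PBS+ICB pool 2), such as Folr2 (-2.57), Mmp12 (-2.22), Pf4 (-2.09) and Apoe (-1.95). Inflammatory myeloid genes had 8 higher and 6 lower (median 0.08, percentile 65.3), with Il1a at -1.96 and Cd40 at 1.67. A single cell held 37 of the 50 Il1a UMIs of PBS+IgG. Glycolysis and hypoxia genes had 2 higher and 15 lower (median -0.48, percentile 0; Eno1 -1.57, Gapdh -1.50), stress genes 12 higher and 3 lower (median 0.49, percentile 99.9, with Fosb 1.67) and p53 targets 4 higher and 9 lower (median -0.07, percentile 27.3; Phlda3 -3.17). All 20 cell cycle genes were lower (median -1.49, percentile 0, with Cdc20 -2.24, Nusap1 -2.04), with -2.58 after removal of cells with markers of another class and -0.50 without doublet removal. Further named genes were Serpina3g (2.76), Cd69 (2.28), the complement gene C3 (2.21), Nr4a2 (2.19), Il15ra (2.18) and Tagap (2.11) on the higher side and Hmgn1 (-2.32), Pmp22 (-2.21), Cd63 (-2.01), Dennd5b (-1.82), Timp2 (-1.76), C1qc (-1.75) and Serpinb6a (-1.73) on the lower side. Pmp22 moved to -3.06 without PBS+ICB pool 2, and Cd274 was at 1.09.

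RNA of other cell types was also found in this class. Cytotoxic effector genes had 14 of 17 members higher (median 1.08, percentile 100; Prf1 2.97, Gzmb 2.69, or 3.315 without PBS+IgG pool 1), and the median was 0.03 after removal of cells with 3 or more CD8 T or NK markers, which were 3.15% of the class in PBS+IgG and 7.97% in PBS+ICB. All 5 measured melanoma pigment genes were lower (median -3.46, percentile 0; -4.37 without PBS+ICB pool 4), with Tyr at -5.90 and Dct at -5.03.

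Type I interferon genes were higher in CD4 T cells, Treg, NK cells and neutrophils of PBS+ICB too. The CD4 T cell median was 1.23 (16 of 16 higher; Oasl1 2.59, Oasl2 2.46), the Treg median 1.05 (12 of 12; Ifit3b 3.94, Ifit3 2.76), the NK median 0.81 (15 of 15; Ifi27l2a 1.42, Ifit2 1.28) and the neutrophil median 2.05 (16 of 16; Ifit3b 2.79, Ifi27l2a 2.48), each at percentile 100. In B cells, 2 of the 4 measured members were higher (median 0.01, percentile 26.8). T helper genes in CD4 T cells had 6 higher and 4 lower (median 0.28, percentile 81.6), with Ifng at 2.23 and Il2 at -1.02. Treg activation genes had 9 higher and 6 lower (median 0.06, percentile 79.3), with the chemokine receptor gene Ccr8 at -1.29 and Gzmb at 0.97. In NK cells 15 of 18 cytotoxic genes were higher (median 0.60, percentile 100), led by the chemokine genes Ccl3 (3.86) and Ccl4 (3.54) and by Ifng (1.73). In neutrophils 12 of 13 inflammatory genes were lower (median -0.53, percentile 0, with Il1a -1.66, Cxcl1 -1.58).

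For the shares, the ranges of CD8 T cells over hashtag pools overlapped (0 to 30.1% in PBS+IgG and 4.41 to 53.4% in PBS+ICB), while those of Treg did not (8.00 to 16.4% and 1.38 to 4.09%). Among cells with an antibody barcode the log2 ratios were 1.07 for CD8 T cells, 2.21 for CD4 T cells and -2.26 for Treg, and that of neutrophils turned to 0.36; without PBS+ICB pool 2 the neutrophil ratio was -2.02.

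The second comparison, CTX+IgG against PBS+IgG, asks what differs 14 days after cyclophosphamide alone. CD8 T cells (log2 ratio 1.05, 0.84 to 1.25; 2.06-fold) and NK cells (1.65, 1.40 to 1.90) took higher shares, and neutrophils (-2.87) and B cells (-3.44) lower ones. A few neutrophils of CTX+IgG carried RNA of granule enzymes made by marrow precursors. Elane was found in 5 of 278 cells, with 621 of its 753 UMIs in 1 cell, and Mpo in 3. Neither gene had a UMI in the neutrophils of PBS+IgG. Monocytes and macrophages, taken as 1 class, carried less Arg1, the arginase that depletes arginine, and less of the glycolytic genes. Monocytes and macrophages were at 0.55, CD4 T cells at -0.43 and Treg at -0.22.

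In CD8 T cells the largest cluster differed, cluster 3 in PBS+IgG (37.4%) and cluster 0 in CTX+IgG (37.9%). Type I interferon genes had 13 higher and 3 lower (median 0.59, percentile 100), among them Ifi27l2a (1.29), Bst2 (1.25) and Isg15 (1.21). Interferon-gamma genes had 13 higher and 4 lower (median 0.28, percentile 100; Iigp1 0.87, Cxcl10 -0.78), and 9 of 10 MHC class I genes were higher (median 0.22, percentile 91.8, with Psmb10 0.51). Cytotoxic genes had 9 higher and 10 lower (median -0.01, percentile 8.32), with Gzma at 2.41, Ifng at 1.16, Gzmb at 0.47, Gzmf at -1.84 and Serpinb6b at -1.69. Terminal effector genes had 2 higher and 6 lower (median -0.40, percentile 4.66), with Klrg1, a receptor of effector T cells, at 1.28 and Cx3cr1 at -2.23. The exhaustion list had 9 higher and 8 lower (median 0.01, percentile 37.5; 0.24 with TMM), with Nrn1 at -0.92 and Cd244a at -0.75, while Pdcd1 was at 0.07, Ctla4 at 0.41 and Tox at -0.64. Naive and memory genes had 3 higher and 10 lower (median -0.76, percentile 0.02), with Id3 at -1.71, Tcf7 at -0.90 and Xcl1 at 0.90; with a minimum of 200 UMIs the median turned to 0.02. Among cell cycle genes 8 were higher and 12 lower (median -0.14, percentile 1.50; Mki67 -0.66, Top2a -0.59) and turned to 0.08 with TMM. Stress genes had 13 higher and 1 lower (median 0.89, percentile 100, with Fos 2.08, Dusp1 1.56), p53 targets 3 higher and 9 lower (median -0.48, percentile 2.05; Plk2 -1.62), glycolysis genes 8 higher and 8 lower (median -0.01, percentile 48.04, with Ndrg1 -1.36, Gapdh -1.20). MHC class II genes had 3 higher and 3 lower (median 0.01, percentile 81.3), with 1.97 under the per-cell gate, -0.42 after removal of cells with markers of another class, -1.215 without CTX+IgG pool 1 and 0.72 without PBS+IgG pool 5.

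Named genes of CD8 T cells on the higher side included Ifitm1 (6.29, 1 UMI in PBS+IgG, interval 3.80 to 11.60), the monocyte chemokine genes Ccl2 (3.41) and Ccl12 (2.83), Ccr2 (2.03), Tyrobp (1.78, or 0.96 without CTX+IgG pool 1) and Gclm (1.77). Lower ones were Serpinb9b (-3.42), Cxcl2 (-3.12), Hist1h2ap (-1.96), Hist1h4h (-1.84) and Slc16a11 (-1.63). Cxcl2 turned to 1.44 without PBS+IgG pool 5 and was at -4.76 without CTX+IgG pool 2. Serpinb9b moved to -2.81 without PBS+IgG pool 5. Gzmf moved to -2.82 without CTX+IgG pool 1 and to -2.56 after removal of cells with markers of another class. Without PBS+IgG pool 1 Tyrobp was at 2.38 and Ccl12 at 2.24.

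In monocytes and macrophages cluster 2 was again the largest (48.9% of CTX+IgG), with 34.2% in cluster 6. Cluster 6 held 12.1% of PBS+IgG, and the macrophage cluster 13 held 36.6% of PBS+IgG and 16.9% of CTX+IgG. Whether the class values follow this mix was not tested, here or in the other comparisons. Suppressive macrophage genes had 1 higher and 14 lower (median -1.48, percentile 0): Arg1 was at -2.84 (-2.92 to -2.75; 130 against 925 CPM), Pf4 at -2.40, the osteopontin gene Spp1 at -2.01 and the heme oxygenase gene Hmox1 at -1.75. Arg1 moved to -3.60 without CTX+IgG pool 1. All 17 glycolysis and hypoxia genes were lower (median -1.04, percentile 0), such as Gapdh (-1.82), Ero1l (-1.74) and Vegfa (-1.53). Interferon-gamma genes had 18 higher and 1 lower (median 0.82, percentile 100), with Cxcl9 at 2.31, Cxcl10 at 2.12 and Socs1 at 2.12; Cxcl9 was at 3.02 without PBS+IgG pool 5, and Cd274 at -0.09. The type I interferon list had 16 higher and 1 lower (median 0.34, percentile 99.9; Zbp1 1.08), all 10 MHC class I genes (median 0.51, percentile 100.0, with Psmb10 0.96) and all 8 MHC class II genes (median 0.20, percentile 71.6; H2-DMa 0.76) were higher. Inflammatory myeloid genes had 7 higher and 7 lower (median -0.01, percentile 40.1), with Cxcl3 at -4.05 and Nos2 at -2.68. The cell cycle list had 2 higher and 18 lower (median -0.25, percentile 2.55, with Nusap1 -0.92), with -1.30 after removal of cells with markers of another class, 0.56 among cells with an antibody barcode, -0.96 after removal of the highest Scrublet scores and -1.51 without CTX+IgG pool 1. Stress genes had 9 higher and 6 lower (median 0.15, percentile 75.5; Hspa1b -2.46) and p53 targets 4 higher and 10 lower (median -0.18, percentile 23.1, with Phlda3 -1.28). The lower named genes were Igfbp4 (-2.39), Ecm1 (-2.27), Fkbp5 (-2.12, or -2.70 after removal of cells with markers of another class), Stab1 (-1.995, or -2.65 without CTX+IgG pool 1), Cd24a (-1.81) and Dynlt1b (-1.76).

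Most named genes on the higher side of this class are genes of T and NK cells: Gzma (4.26), Tnfrsf4 (3.69), Ctla4 (2.83), Lag3 (2.47), Prf1 (2.40) and Pdcd1 (2.25), beside Ch25h (2.22). Cells with 3 or more CD8 T or NK markers were 12.4% of the class in CTX+IgG, and without them Gzma was at 2.80 and the median of cytotoxic genes (15 of 17 higher; 2.14, percentile 100) was 0.39. That median was 0.81 without doublet removal, 1.19 without CTX+IgG pool 1 and 1.52 with a minimum of 20 UMIs. A single cell held 23 of the 30 Gzma UMIs of PBS+IgG, and without PBS+IgG pool 1 Gzma was at 6.15. Without CTX+IgG pool 1, Tnfrsf4 was at 2.46, Ctla4 at 1.72, Lag3 at 1.74, Pdcd1 at 0.93 and Ch25h at 1.27, and without PBS+IgG pool 3 Lag3 was at 3.14 and Prf1 at 2.99. All 5 melanoma genes were lower (median -3.12, or -1.97 without doublet removal, percentile 0; Dct -4.62, Tyr -4.24).

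All 9 measured granulocyte progenitor genes were higher in neutrophils (median 7.01, percentile 100, with 4 members given as bounds against 0 UMIs in PBS+IgG). The cathelicidin gene Camp was at 8.74 and the protease gene Prtn3 at 7.76. Cluster 4 held 92.1% of the neutrophils of PBS+IgG and cluster 17 held 91.0% of those of CTX+IgG; without CTX+IgG pool 2 the progenitor median was 5.35, and after removal of cells with Elane or Mpo UMIs it was 5.12, over 4 measured members. Few cells carried these genes: Camp was found in 19 of the 278 neutrophils of CTX+IgG and Prtn3 in 9, with 428 of its 563 UMIs in 1 cell. Inflammatory genes had 1 higher and 11 lower (median -1.85, percentile 0.05), with Nos2 at -4.81 and Cxcl3 at -4.12, and type I interferon genes 7 higher and 7 lower (median 0.03, percentile 37.6, with Bst2 3.31). In NK cells 14 of 19 cytotoxic genes were higher (median 0.60, percentile 100), with Gzme at 5.37 and Gzmd at 3.79, and 15 of 16 type I interferon genes (median 0.41, percentile 100.0; Oasl2 1.90). In Treg, activation genes had 11 higher and 5 lower (median 0.27, percentile 98.98, with Itgae 1.17, Gzmb 1.09) and type I interferon genes 9 higher and 2 lower (median 0.66, percentile 100; Ifit3 1.62). In CD4 T cells, type I interferon genes had 9 higher and 1 lower (median 0.29, percentile 84.2, with Isg20 0.82) and T helper genes 4 higher and 2 lower (median 0.08, percentile 41.1; Ifng 1.203).

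The NK share was lower among the deeper cells with an antibody barcode, at 4.25% in PBS+IgG and 5.65% in CTX+IgG (log2 ratio 0.41). The neutrophil ratio was -1.67 among those cells and -3.78 under the stricter filter, and the pool ranges of CD8 T cells overlapped (12.3 to 63.5% in CTX+IgG).

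The third comparison, CTX+ICB against PBS+IgG, sets both treatments against neither. CD8 T cells were 5.82-fold more frequent (log2 ratio 2.54, 2.35 to 2.74) and were the majority of CTX+ICB, while neutrophils (-4.71), B cells (-3.68), conventional dendritic cells (-2.04), monocytes and macrophages (-1.41) and Treg (-1.16) took lower shares. These CD8 T cells carried more Gzma and Klrg1 and less RNA of the exhaustion list. Monocytes and macrophages carried more of the interferon-gamma genes and less Spp1 and Apoe. CD4 T cells were at 1.68 and NK cells at 0.33.

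In CD8 T cells the largest cluster was cluster 0 in CTX+ICB (47.8%) against cluster 3 in PBS+IgG (37.4%). The exhaustion list had 2 higher and 15 lower (median -0.40, percentile 0; -0.15 under the per-cell gate), with Nrn1 at -3.10, Ccrl2 at -1.66, the transcription factor gene Tox at -1.25 and Tnfrsf9 at -1.20, beside Pdcd1 at -0.74 and Ctla4 at -0.03. Terminal effector genes had 5 higher and 3 lower (median 0.24, percentile 97.4), with Klrg1 at 1.90 and Cx3cr1 at -2.03. Cytotoxic genes had 9 higher and 10 lower (median -0.26, percentile 0.09; 0.03 under the stricter filter), with Gzma at 4.02 (314 against 19.3 CPM), Gzmb at 1.05, Ifng at 0.66 and Gzmf at -2.04. Naive and memory genes had 6 higher and 7 lower (median -0.07, percentile 55.7, with Id3 -3.07, Tcf7 -0.22) and a median of -0.875 under the per-cell gate. Type I interferon genes had 16 higher and 1 lower (median 1.196, percentile 100; Isg15 1.78, Ifi27l2a 1.74), interferon-gamma genes 16 higher and 1 lower (median 0.70, percentile 100, with Iigp1 1.31), and all 10 MHC class I genes were higher (median 0.47, percentile 100.0; H2-K1 0.74). Stress genes had 13 higher and 1 lower (median 0.67, percentile 100, with Fosb 3.25, Fos 2.39), cell cycle genes 7 higher and 13 lower (median -0.06, percentile 23.2; Mcm6 -0.47, Mki67 0.24), p53 targets 9 higher and 5 lower (median 0.09, percentile 89.0, with Plk2 -1.97) and glycolysis genes 6 higher and 10 lower (median -0.24, percentile 1.72; Gapdh -1.37). MHC class II genes had 1 higher and 5 lower (median -2.05, percentile 0), with Cd74 at -2.50. The list was at -1.11 under the per-cell gate, -1.15 without PBS+IgG pool 5, -2.78 without CTX+ICB pool 3 and -2.91 after removal of the highest Scrublet scores.

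Named genes of CD8 T cells on the higher side included Ifitm1 (8.77, 6.29 to 14.07) and Esm1 (5.99, 3.50 to 11.30), each with 1 UMI in PBS+IgG, the cholesterol exporter gene Abcg1 (4.02) and Ccr2 (3.19). The integrin gene Itgax was at least 15.2-fold and Gcg at least 10.6-fold higher, with 0 UMIs in PBS+IgG. Lower ones were Cxcl2 (-10.96, -16.27 to -8.48, 1 UMI in CTX+ICB; -9.12 without CTX+ICB pool 4), Slc16a11 (-2.95), the enkephalin gene Penk (-2.94), Igfbp7 (-2.77), Fcrl6 (-2.73) and Bmyc (-2.60). Without CTX+ICB pool 4 Igfbp7 was at -3.49, without CTX+ICB pool 1 Fcrl6 at -3.37, and without PBS+IgG pool 1 Esm1 at 3.82 and Abcg1 at 3.44.

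In monocytes and macrophages (cluster 2, 58.2% of CTX+ICB) all 19 interferon-gamma genes were higher (median 1.65, percentile 100): Cxcl10 was at 3.38, Socs1 at 3.26, Cxcl9 at 3.24 and the guanylate-binding protein genes Gbp4 and Gbp5 at 2.74. All 16 type I interferon genes (median 1.15, percentile 100, with Ifit1 1.68) and all 10 MHC class I genes (median 1.04, percentile 100; Nlrc5 1.49) were higher, and 6 of 8 MHC class II genes (median 0.23, percentile 88.5, with Ciita 1.50). Suppressive genes had 1 higher and 14 lower (median -1.47, percentile 0), with Spp1 at -2.85 (-3.54 without CTX+ICB pool 2), Pf4 at -2.74 and Folr2 at -2.52. Glycolysis genes had 1 higher and 16 lower (median -1.04, percentile 0; Gapdh -2.07), cell cycle genes 3 higher and 17 lower (median -0.57, percentile 0.02, with Ccnb2 -2.21), inflammatory genes 6 higher and 8 lower (median -0.15, percentile 11.1; Cxcl3 -3.81, Cd40 1.73), stress genes 9 higher and 6 lower (median 0.29, percentile 97.2, with Hspa1b -4.30) and p53 targets 3 higher and 7 lower (median -0.14, percentile 19.9; Plk2 -1.27). The cell cycle median was -1.44 after removal of cells with markers of another class and -2.51 at resolution 2. Other named genes were Calhm6 (3.03), Ly6i (2.90), C3 (2.64) and Iigp1 (2.51), and on the lower side Lcn2 (-4.13, or -4.74 without CTX+ICB pool 1 and -4.90 after removal of cells with markers of another class), Ddit4 (-3.12), Cd81 (-3.06), Eno1b (-2.83), Ctsl (-2.66), Ms4a7 (-2.48) and Apoe (-2.27). That removal covered CD8 T and NK markers only. In the neutrophils of PBS+IgG, Lcn2 had 7735 UMIs, found in 511 of 662 cells, and neutrophil RNA in this class was not tested. Cd274 was at 1.04. Cytotoxic genes had 11 of 14 higher (median 1.31, percentile 100, with Gzmb 3.42, or 4.045 without PBS+IgG pool 1; 0.52 after removal of cells with markers of another class), and all 4 melanoma genes were lower (median -4.27, percentile 0, 2 members given as bounds; Dct -6.15), with -3.26 at a minimum of 20 UMIs.

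The 6 measured progenitor genes were higher in neutrophils (median 7.99, percentile 100, 1 member given as a bound; Camp 9.03, in 5 of the 50 neutrophils of CTX+ICB, and Ltf 8.27, in 8; median 6.205 without the cell with Elane), 1 of 12 inflammatory genes was higher (median -1.58, percentile 0.03; Cxcl3 -4.89) and all 13 type I interferon genes were (median 1.25, percentile 99.3, with Bst2 4.27; 0.46 with TMM). In NK cells 16 of 19 cytotoxic genes (median 0.99, percentile 100; Gzme 5.83, Gzmd 4.73, Gzmf 4.43) and all 11 type I interferon genes (median 0.66, percentile 100, with Ifi27l2a 1.77) were higher. Treg activation genes had 6 higher and 9 lower (median -0.13, percentile 10.6; Ccr8 -2.001, Itgae 1.60), and 11 of 12 type I interferon genes were higher in Treg (median 0.78, percentile 100, with Ifit3 1.97). In CD4 T cells T helper genes had 5 higher and 4 lower (median 0.61, percentile 100.0; Cxcr6 1.08, Ifng 1.34), with Il17a at least 3.33-fold higher against 0 UMIs, and type I interferon genes 11 higher and 4 lower (median 0.32, percentile 97.2, with Oasl2 1.41). The pool ranges of CD8 T cells did not overlap between these libraries (44.6 to 71.1% in CTX+ICB). Among cells with an antibody barcode the log2 ratio of CD8 T cells was 1.76, that of Treg -2.02 and that of neutrophils -2.92, and under the stricter filter the neutrophil ratio was -5.38.

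**Figure D2:**
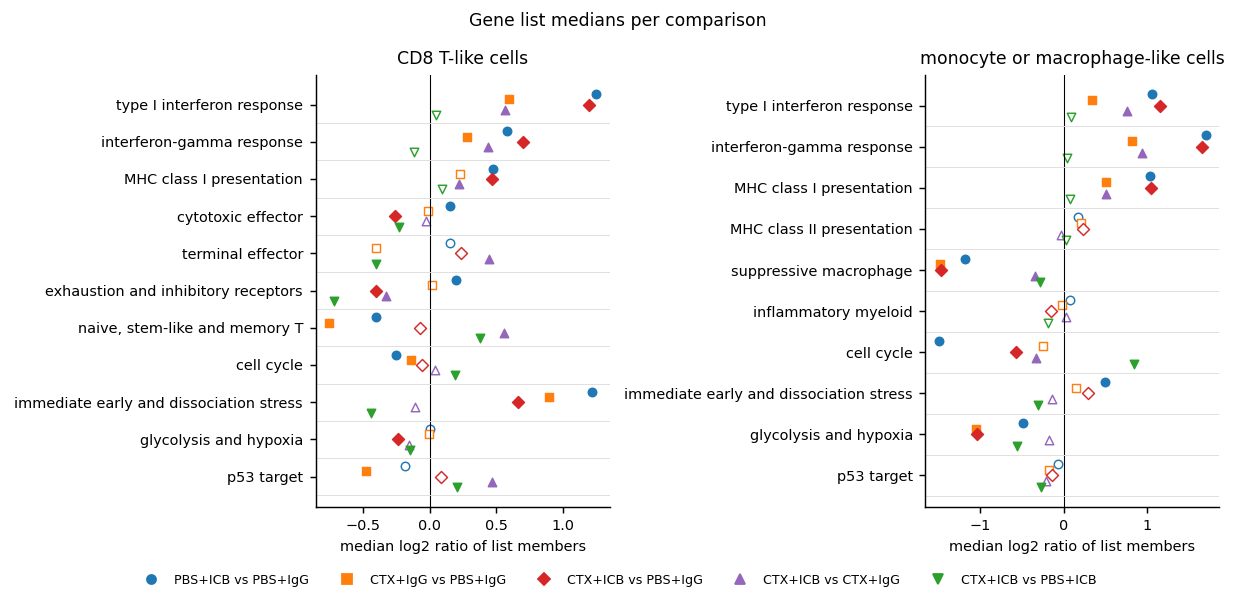
Median log2 ratio of each gene list (horizontal axis) in CD8 T cells and in monocytes and macrophages for the 5 comparisons. Type I interferon genes of CD8 T cells had medians of 1.25, 0.59 and 1.196 in the 3 treated libraries against PBS+IgG, and suppressive macrophage genes -1.17, -1.48 and -1.47.

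The fourth comparison, CTX+ICB against CTX+IgG, asks what blockade adds after cyclophosphamide. CD8 T cells (log2 ratio 1.50, 1.40 to 1.59; 2.82-fold) and CD4 T cells (2.11) were more frequent, and monocytes and macrophages (-1.96), neutrophils (-1.84), NK cells (-1.32) and Treg (-0.94) less frequent. CD8 T cells carried more RNA of S1pr1, the receptor that guides lymphocytes out of tissue, and of interferon-induced genes. They carried less of Nrn1, Ccr8 and Pdcd1. Monocytes and macrophages carried more of the interferon-gamma genes and more Arg1.

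Cluster 0 was the largest CD8 cluster of both libraries (37.9% of CTX+IgG and 47.8% of CTX+ICB), while cluster 3 held 30.1% and 15.6%. The exhaustion list had 2 higher and 15 lower (median -0.33, percentile 0.02), with Nrn1 at -2.18, Rgs16 at -1.15, Ccrl2 at -1.13, Tnfrsf9 at -0.93 and Pdcd1 at -0.80 (-0.86 to -0.74; 262 against 457 CPM). Tox was at -0.62 and Ctla4 at -0.44. All 8 terminal effector genes were higher (median 0.45, percentile 98.2), led by S1pr1 (2.03), Klrg1 (0.62) and Zeb2 (0.61). Naive and memory genes had 8 higher and 5 lower (median 0.56, percentile 99.8), with Lef1 at 1.40, Tcf7 at 0.68, Xcl1 at -2.54 and Ccr7 at -1.61, and turned to -0.03 under the per-cell gate. Cytotoxic genes had 8 higher and 11 lower (median -0.03, percentile 81.0), with Gzma at 1.61, Serpinb6b at 1.11, Gzmc at -1.17, Gzmb at 0.58 and Ifng at -0.51. Antiviral genes of the type I interferon list had 16 higher and 1 lower (median 0.56, percentile 100; Ifi44 1.21, Cmpk2 1.13), interferon-gamma genes 13 higher and 4 lower (median 0.43, percentile 99.9, with Nlrc5 0.90, Cd274 0.78) and MHC class I genes 8 higher and 2 lower (median 0.22, percentile 99.5; H2-D1 0.49). Among p53 targets 11 were higher and 3 lower (median 0.47, percentile 98.9), with Trp53inp1 at 1.37, Zmat3 at 1.16 and the cell cycle inhibitor gene Cdkn1a at 0.79. Cell cycle genes had 11 higher and 9 lower (median 0.04, percentile 89.3, with Mki67 0.90, Top2a 0.59), glycolysis genes 6 higher and 10 lower (median -0.16, percentile 8.61; Ndrg1 0.96) and stress genes 7 higher and 8 lower (median -0.11, percentile 15.6, with Fosb 1.67, Hspa1a -1.46).

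MHC class II genes had 2 higher and 4 lower in CD8 T cells (median -2.12, percentile 0; Cd74 -2.57), with -0.55 without CTX+IgG pool 1, -2.94 without CTX+ICB pool 3, -2.905 after removal of the highest Scrublet scores and -3.42 under the per-cell gate. The complement gene C1qb, a macrophage gene, was also among the lower genes (-2.41, or -0.83 after removal of cells with markers of another class, -1.54 without CTX+IgG pool 1 and -3.05 without CTX+ICB pool 2). Other lower genes were Dapl1 (-3.57), Utf1 (-2.69), Ccr8 (-1.83), Tnfrsf4 (-1.77) and the sterol synthesis genes Fdps (-1.75) and Idi1 (-1.60). Higher ones were Emp1 (2.95, 2.15 to 3.89), Esm1 (2.71), the integrin gene Itgb3 (2.51), Ifitm1 (2.48), Abcg1 (2.23) and Socs2 (2.03).

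Among monocytes and macrophages all 19 interferon-gamma genes (median 0.93, percentile 100, with Iigp1 1.36, Gbp5 1.30) and all 17 type I interferon genes (median 0.76, percentile 100; Ifit2 1.46) were higher, as were 9 of 10 MHC class I genes (median 0.51, percentile 100.0, with Nlrc5 1.01). MHC class II genes had 4 higher and 4 lower (median -0.03, percentile 73.6; Ciita 0.79). Suppressive genes had 5 higher and 10 lower (median -0.34, percentile 0.08), with Arg1 at 2.66 (817 against 130 CPM), Fn1 at 1.14, Folr2 at -1.57 and Apoe at -1.04, and turned to 0.26 without CTX+IgG pool 1. Inflammatory genes had 8 higher and 6 lower (median 0.03, percentile 60.8, with Nos2 2.47, Il1a 1.50), glycolysis genes 7 higher and 10 lower (median -0.18, percentile 11.3; Hk2 0.85), p53 targets 6 higher and 8 lower (median -0.21, percentile 6.95, with Phlda3 -2.16) and stress genes 6 higher and 9 lower (median -0.14, percentile 22.015; Hspa1b -1.84). The cell cycle list had 5 higher and 15 lower (median -0.33, percentile 0.07, with Ccnb2 -1.54); they turned to 0.45 after removal of the highest Scrublet scores and to 1.01 without CTX+IgG pool 1, and were at -2.80 at resolution 2. Named genes were the VEGF receptor gene Flt1 (1.97), C3 (1.50), Tnfaip2 (1.43), Sowahc (1.42), Ddhd1 (1.31), Usp7 (1.25), Jak2 (1.21) and Rnf19b (1.21), and on the lower side Ms4a7 (-2.61), Cd72 (-2.61), Tspan4 (-1.90, or -1.30 without CTX+IgG pool 1) and Il1r2 (-1.90). Cd274 was at 1.12. Some T and NK cell genes were lower in this class, with Gzma at -7.29 (2 UMIs in CTX+ICB; -2.97 after removal of cells with markers of another class), Xcl1 at -5.15 (-3.18 without CTX+ICB pool 4), Tnfrsf4 at -2.18 (-0.95 without CTX+IgG pool 1, -3.04 without CTX+ICB pool 2) and Klrc1 at -1.98. Others were not: 6 genes of the T cell receptor complex and CD8 summed to 534 CPM in CTX+IgG and 515 CPM in CTX+ICB, and Pdcd1 was at -0.09 (1.23 without CTX+IgG pool 1). The cytotoxic list had 6 higher and 11 lower (median -0.08, percentile 19.7; -0.76 among cells with an antibody barcode), and Gzmb, at 0.32, turned to -2.11 after removal of cells with markers of another class and was at 1.88 without CTX+IgG pool 1.

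In neutrophils 8 of 9 type I interferon genes were higher (median 0.96, percentile 99.9; Rsad2 2.59). Progenitor genes had 4 higher and 5 lower (median -0.05, percentile 74.95, with Mpo -6.26, Ltf 1.26; 1.04 without CTX+IgG pool 2 and 1.08 without the cells with Elane or Mpo UMIs) and inflammatory genes 4 higher and 5 lower (median -0.34, percentile 32.7; Ccl3 1.47). Cluster 17 held 91.0% of the neutrophils of CTX+IgG and 32.0% of those of CTX+ICB. NK cells had 15 of 19 cytotoxic genes higher (median 0.34, percentile 100, with Gzmk 1.44, Gzmf 1.28) and type I interferon genes 10 higher and 6 lower (median 0.19, percentile 88.3; Ifit2 0.69). In CD4 T cells type I interferon genes had 5 higher and 10 lower (median -0.04, percentile 54.8, with Ifit2 1.83, Oasl2 -0.88) and T helper genes 6 higher and 3 lower (median 0.08, percentile 79.995; Il17a 1.35). Treg activation genes had 9 higher and 8 lower (median 0.04, percentile 90.4, with Ccr8 -1.60, Klrg1 -1.47) and Treg type I interferon genes 6 higher and 6 lower (median 0.07, percentile 92.1; Cmpk2 1.31). Pool ranges of CD8 T cells overlapped, and those of CD4 T cells and Treg did not. Among cells with an antibody barcode the log2 ratio was 3.08 for CD4 T cells, -1.53 for Treg, -1.25 for neutrophils and -0.31 for NK cells.

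The fifth comparison, CTX+ICB against PBS+ICB, asks what cyclophosphamide adds to blockade. CD8 T cells were 1.82-fold more frequent (log2 ratio 0.86, 0.78 to 0.95), and neutrophils (-3.49), B cells (-2.31) and monocytes and macrophages (-1.09) less frequent. CD8 T cells carried more of Klrg1, Il7r (the interleukin-7 receptor) and Lef1 and less of most exhaustion genes, of stress genes and of Zfp683, the Hobit gene of tissue-resident T cells. CD4 T cells were at 0.13, Treg at 0.16 and NK cells at -0.39.

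Within CD8 T cells the largest cluster was cluster 3 in PBS+ICB (36.9%) and cluster 0 in CTX+ICB (47.8%). The exhaustion list had 1 higher and 16 lower (median -0.72, percentile 0): Nrn1 was at -2.79, Rgs16 at -1.23, Ccrl2 at -1.13, Tox at -0.99, Ctla4 at -0.89 and Pdcd1 at -0.72. Naive and memory genes had 8 higher and 5 lower (median 0.37, percentile 100), with Il7r at 1.19, Lef1 at 0.83, Slamf6 at 0.83, Tcf7 at 0.19 and Xcl1 at -1.34; the median turned to -0.53 under the per-cell gate and to -0.02 at resolution 0.5. Terminal effector genes had 2 higher and 6 lower (median -0.41, percentile 0.07), with Klrg1 at 2.02 (1.83 to 2.21), S1pr1 at 1.01 and Klre1 at -0.85. Cytotoxic genes had 8 higher and 11 lower (median -0.23, percentile 0.04), with Gzma at 1.08, Gzmk at 0.71, Ccl3 at -0.94 and the perforin gene Prf1 at -0.80. Gzmb was at 0.08 and turned to -0.22 without CTX+ICB pool 1, and Ifng was at -0.69. Cell cycle genes had 17 higher and 3 lower (median 0.19, percentile 100.0, with Birc5 0.45, Mki67 0.21), and p53 targets 10 higher and 4 lower (median 0.20, percentile 100.0; Bbc3 0.91, Trp53inp1 0.79), which turned to -0.05 without CTX+ICB pool 1. Stress genes had 1 higher and 14 lower (median -0.44, percentile 0, with Atf3 -1.63, Hspa1a -1.56, Hspa1b -1.50). Type I interferon genes had 10 higher and 7 lower (median 0.04, percentile 87.2; Ifi44 1.64), interferon-gamma genes 6 higher and 12 lower (median -0.12, percentile 8.05, with Cxcl9 -1.41, Cd274 -0.12), MHC class I genes 7 higher and 3 lower (median 0.09, percentile 89.2; Psmb9 0.29), glycolysis genes 5 higher and 11 lower (median -0.15, percentile 2.02, with Eno1 0.80) and MHC class II genes 1 higher and 5 lower (median -0.30, percentile 3.54; H2-Aa -1.01). The MHC class II median was -1.44 without doublet removal and 0.10 after removal of cells with markers of another class.

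Named genes of CD8 T cells on the higher side were Esm1 (1.96), Dynlt1f (1.71), Abcg1 (1.68), Ftl1-ps1 (1.59), the annexin gene Anxa1 (1.56), Hist2h2bb (1.22) and Cmah (1.11). Lower ones were Ier5l (-2.36), Zfp683 (-2.20), Ociad2 (-1.78), Adgrg1 (-1.75), Cd200r1 (-1.64) and Idi1 (-1.59).

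In monocytes and macrophages interferon-gamma genes had 11 higher and 8 lower (median 0.04, percentile 88.4, with Cxcl9 0.59), type I interferon genes 9 higher and 8 lower (median 0.09, percentile 96.3; Ifit3b 0.71), MHC class I genes 6 higher and 4 lower (median 0.08, percentile 89.4, with H2-K1 0.34) and MHC class II genes 5 higher and 3 lower (median 0.03, percentile 67.1; H2-DMb1 -0.48). Glycolysis and hypoxia genes had 1 higher and 16 lower (median -0.56, percentile 0, with Vegfa -1.19, Ero1l -1.03). Suppressive genes had 5 higher and 9 lower (median -0.28, percentile 0.01; Mmp12 1.73, Spp1 -1.68) and turned to 0.18 without PBS+ICB pool 2. Inflammatory genes had 2 higher and 12 lower (median -0.18, percentile 3.17, with Cxcl3 -2.52, Il1a 1.78), stress genes 1 higher and 14 lower (median -0.31, percentile 0.01; Hspa1b -3.90) and p53 targets 2 higher and 10 lower (median -0.27, percentile 2.19, with Sesn2 -1.13). Cell cycle genes had 17 higher and 1 lower (median 0.83, percentile 100; Pclaf 1.22), with a reversed median of -1.31 at resolution 2. Cytotoxic genes had 9 higher and 7 lower (median 0.17, percentile 99.6, with Gzma -4.85), and turned to -0.07 after removal of cells with markers of another class, to -0.11 with a minimum of 200 UMIs and to -0.05 without CTX+ICB pool 1. The neutrophil gene S100a9 was at -7.36 (0.547 against 90.04 CPM, 1 UMI in CTX+ICB; -5.40 without CTX+ICB pool 4). Other lower genes were the sterol genes Cyp51 (-1.28) and Insig1 (-1.21), Ier3 (-1.16), Rnf11 (-0.95), Shc1 (-0.92) and Wdr37 (-0.87), and the higher ones Paxbp1 (0.78), Smim11 (0.69), Cep83 (0.54), Lsm8 (0.54), Pank2 (0.49), Ptpmt1 (0.43), Pkn2 (0.43) and Mien1 (0.38). In this class and comparison the pools did not overlap for 146 of 8400 genes (1.74%), against 0.794% by chance. Pools that do not overlap therefore say little about any single gene named here. Cd274 was at -0.05.

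In CD4 T cells all 16 type I interferon genes were lower (median -0.97, percentile 0; Rsad2 -1.96, Ifit3 -1.56), and T helper genes had 3 higher and 8 lower (median -0.07, percentile 66.0), with the interleukin-17A gene Il17a at 5.56. In Treg, type I interferon genes had 1 higher and 12 lower (median -0.33, percentile 0.34, with Ifit3b -1.50) and activation genes 4 higher and 13 lower (median -0.19, percentile 1.34; Itgae 0.73), which turned to 0.01 after removal of the highest Scrublet scores. NK cells had 8 cytotoxic genes higher and 11 lower (median -0.05, percentile 30.1, with Gzmf 9.03, Gzmd 4.99) and type I interferon genes 4 higher and 11 lower (median -0.29, percentile 1.72; Oasl1 -0.61). In neutrophils all 6 progenitor genes were higher (median 8.74, percentile 100.0, 2 members given as bounds; Ltf 9.29 and Ngp 8.59, in 8 and 6 cells of CTX+ICB), inflammatory genes had 2 higher and 9 lower (median -0.84, percentile 17.6, with Cxcl3 -4.36) and type I interferon genes 5 higher and 11 lower (median -0.74, percentile 9.07; Ifit3b -2.47). Cluster 4 held 96.0% of the neutrophils of PBS+ICB and 68.0% of those of CTX+ICB. Without PBS+ICB pool 2 the neutrophil share was at -2.69, under the stricter filter at -4.20, and the pool ranges of CD8 T cells overlapped.

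As a second count of CD8 T cells, a per-cell gate took 14.1% of PBS+IgG, 37.1% of PBS+ICB, 24.99% of CTX+IgG and 59.5% of CTX+ICB. With each cell thinned to 1000 UMIs the gate took 10.7%, 31.7%, 20.3% and 51.2%, leaving out 65, 110, 309 and 133 shallower cells. The same gate took 0%, 0.259%, 3.96% and 0% of neutrophils and at most 1.08% of NK cells, classes that should lack the gated genes. It was not read in monocytes and macrophages. Of these, 7.63 to 9.80% in the treated libraries carried at least 3 of 6 T cell receptor complex and CD8 genes, so the gate may take more of that class. Of all T cells, CD8 T cells were 36.8%, 63.7%, 63.6% and 77.9% and Treg 21.8%, 4.70%, 15.6% and 3.54%.

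Antibodies against PD-1 (CD279) and CTLA-4 (CD152), the targets of the injected antibodies, were measured on CD8 T cells beside the RNA. CD279 stood at 17277 CPM in PBS+IgG (133 cells), 9192 in PBS+ICB (1780 cells), 15132 in CTX+IgG (574 cells) and 9713 in CTX+ICB (1952 cells). The log2 ratio was -0.91 (-0.97 to -0.85) with blockade alone, -0.19 for CTX+IgG and -0.83 for CTX+ICB against PBS+IgG, -0.64 for CTX+ICB against CTX+IgG and 0.08 against PBS+ICB. Pdcd1 RNA in the same cells was 433 CPM, 430.1 CPM, 457 CPM and 265 CPM. Monocytes and macrophages, used as background, bound 5366, 5113, 5771 and 4416 CPM of CD279. CD152 on CD8 T cells was at 11668, 10315, 13855 and 10309 CPM; its ratio for CTX+IgG against PBS+IgG (0.25) turned to -0.04 with isotype scaling. On Treg, CD279 was at 12237, 6603, 7433 and 5773 CPM and Pdcd1 RNA at 314 CPM, 111 CPM, 164 CPM and 66.3 CPM, and CD152 at 10187, 9932, 11541 and 11428 CPM. On monocytes and macrophages CD152 was at 10490, 10322, 14089 and 8996 CPM.

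**Figure D3:**
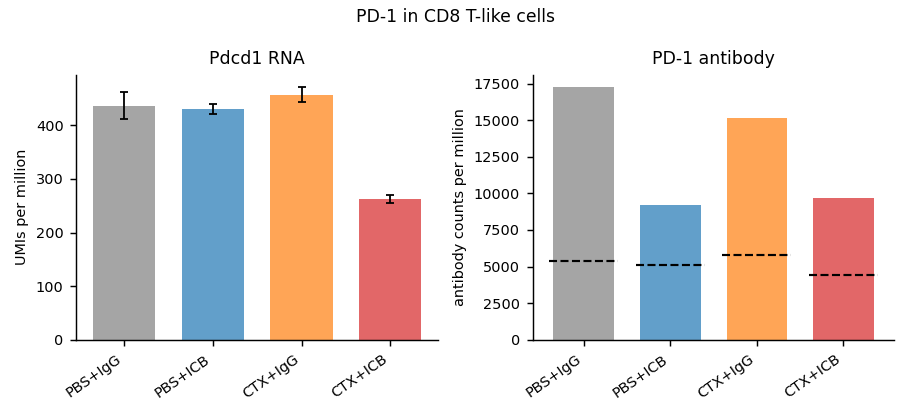
PD-1 antibody (CD279) counts and Pdcd1 RNA in CD8 T cells, both in CPM, for the 4 libraries, with the antibody level of monocytes and macrophages as background. The antibody was at 9192 CPM in PBS+ICB against 17277 in PBS+IgG, where Pdcd1 RNA was 430.1 and 433 CPM.

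Ly-6C, a surface protein of effector and memory CD8 T cells in mice, was higher with blockade than without. It was also higher with cyclophosphamide than without, both with IgG and with blockade. It was at 12788 CPM in PBS+IgG, 45307 in PBS+ICB, 25417 in CTX+IgG and 72085 in CTX+ICB, a log2 ratio of 1.82 with blockade alone, 2.495 for CTX+ICB against PBS+IgG and 1.50 against CTX+IgG. GITR (CD357), a costimulatory receptor, was lower in all 3 treated libraries (-1.05, -0.70 and -1.26 against PBS+IgG), and ICOS (CD278) was at 1.59 and CX3CR1 at -1.16 in CTX+ICB against PBS+IgG. KLRG1 was at 1.76 in CTX+ICB against PBS+ICB (CLR 0.77) and OX40 (CD134) at -0.997 against CTX+IgG, beside CXCR5 (CD185) at -0.83. For several other named antibodies 1 cell held a large part of the counts, 53.2% of Ly-6G/Ly-6C, 61.6% of CD107a and 47.1% of CD1d counts in CTX+ICB and 75.04% of Siglec-H counts in CTX+IgG.

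T cell receptor beta V gene use was read from the RNA of CD8 T cells as a coarse stand-in for clones. At 224 cells per library, the effective number of Trbv genes (inverse Simpson) was 8.55 in PBS+IgG, 11.4 in PBS+ICB (9.98 to 13.0 over draws), 8.70 in CTX+IgG (7.40 to 10.0) and 11.1 in CTX+ICB (9.24 to 13.0). The most used gene was Trbv20 in PBS+IgG (21.0% of cells) and PBS+ICB (14.5%) and Trbv19 in CTX+IgG (22.8%) and CTX+ICB (20.2%). Pools of 1 library differed in their most used gene, such as Trbv16, Trbv12-2 and Trbv31 in CTX+IgG. With only cells that had a single Trbv gene, at 160 cells, the numbers were 7.72, 10.4, 7.89 and 11.5; the most used gene of PBS+IgG was then Trbv13-1 (21.25%), and that of CTX+IgG pool 1 Trbv19 in place of Trbv16.

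Some of the summed values above rest on 1 cell. In CD8 T cells a single cell held 293 of the 302 Cxcl2 UMIs and 51 of the 79 Cxcl10 UMIs of PBS+IgG, 428 of the 475 Ccl2 UMIs and 208 of the 226 Ccl12 UMIs of CTX+IgG, and 165 of the 210 Gcg UMIs of CTX+ICB. In NK cells of CTX+IgG 1 cell held 775 of the 1329 Gzme UMIs and 1 cell 848 of the 1025 Gzmf UMIs, while all 756 Gzmf UMIs of CTX+ICB lay in 2 cells. In neutrophils of CTX+IgG 1 cell held 316 of the 337 Mpo UMIs. In monocytes and macrophages 1 cell held 288 of the 537 Spp1 UMIs of CTX+ICB and 1 cell 37 of the 50 Il1a UMIs of PBS+IgG.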

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

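Of the tests below, the reading of S100a8 and S100a9 in the neutrophils of PBS+ICB pool 2 and a free RNA test that was later replaced were set before their results were seen. The tests of the PD-1 antibody, of hashtag 2, of UMIs per barcode, of doublets and of free RNA in its present form were chosen after the results were seen.

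In 5 cases a class share stood out because 1 hashtag pool lay far from the other pools of its library. CD8 T cells were 4.409% of PBS+ICB pool 2, where the nearest pool had 41.884%, and 44.643% of CTX+ICB pool 5, against 65.226%. CD4 T cells were 6.452% of CTX+IgG pool 3 (2 of its 31 cells), against 2.048%, and 17.857% of CTX+ICB pool 5, against 10.124%. Neutrophils were 59.370% of PBS+ICB pool 2, against 1.703% in the nearest pool. Such a gap was looked for in 24 groups of pools, and chance marks about 1 in 20 groups.

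Another 9 results stood out because a treatment was followed by opposite signs with and without the other treatment. These differences between groups were not tested, and 58 pairs were looked at. For blockade, the first value is with cyclophosphamide and the second without: the NK share had log2 ratios of -1.319 and 0.722, the exhaustion list in CD8 T cells -0.332 and 0.195, and the naive and memory list 0.557 and -0.408. For cyclophosphamide, the first value is with blockade and the second without. The NK share had -0.393 and 1.648, and the share of monocytes and macrophages -1.085 and 0.545. In CD8 T cells the naive and memory list had 0.374 and -0.757, the cell cycle list 0.190 and -0.145, p53 targets 0.203 and -0.476, and stress genes -0.443 and 0.894. Of these pairs, 4 did not keep opposite signs under every alternative. For the naive and memory list the blockade value with cyclophosphamide turned to -0.029 and the cyclophosphamide value with blockade to -0.53 under the per-cell gate; the latter was -0.016 at resolution 0.5, and the cyclophosphamide value without blockade was 0.023 at 200 UMIs. The cell cycle value without blockade turned to 0.08 with TMM, and the p53 value with blockade to -0.049 without CTX+ICB pool 1.

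PD-1 antibody counts on CD8 T cells were lower with blockade than without. Less Pdcd1 RNA is argued against for CD8 T cells of the PBS pair. There the RNA was nearly equal (log2 ratio -0.010) and the antibody excess over background was lower by -1.535 (-1.679 to -1.383) beyond the RNA ratio. In Treg of this pair the RNA was itself lower (-1.501), and the excess lay -0.703 (-1.345 to -0.113) beyond it. That is smaller than the Treg difference between the IgG libraries given below, so it decides nothing for Treg. These intervals cover counting error only, with 1 library on each side. For the CTX pair the excess followed the RNA in CD8 T cells (-0.037, -0.144 to 0.068), but not in Treg (1.016, 0.261 to 1.811). A different antibody background is argued against for the PBS pair by the ratio after isotype scaling (-0.884, -0.949 to -0.820). For the CTX pair it may account for part of the difference, whose ratio of -0.64 was -0.351 (-0.386 to -0.316) after the same scaling. Masking by the injected antibody stays open, in both blockade libraries or in PBS+ICB alone. The pairs differed by 1.499 (1.239 to 1.747), an interval for counting error only, while CTX+IgG and PBS+IgG, both without injected antibody, also differed beyond the RNA, by -0.426 (-0.582 to -0.265) in CD8 T cells and -1.111 (-1.553 to -0.662) in Treg. Less PD-1 protein per RNA in PBS+ICB stays open too.

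Neutrophils were concentrated in PBS+ICB pool 2, which held 377 of the 399 tagged ones (94.5%). Binding of hashtag 2 to neutrophils alike in every library is argued against, since 15.574% (9.65 to 23.2%) of the tagged neutrophils in the other 3 libraries carried it, with 5 of 45 in CTX+IgG and 3 of 28 in CTX+ICB, against 25.5% and 36.1% of all tagged cells there. In PBS+IgG, however, 22.449% (11.8 to 36.6%) of the tagged neutrophils carried hashtag 2, against 3.67% of all tagged cells, so binding in the PBS libraries may contribute. Empty droplets with the library's free RNA are argued against, because free RNA loads each barcode alike. S100a8 plus S100a9 had a mean of 247 UMIs per barcode in these cells and 0.659 in the other classes of the library, a ratio of 374.397 (231 to 675), and 91.7% of the other barcodes had none. The level of 25.963 times the library mean decides nothing by itself, since the class was named from markers that include these genes. What the pools stand for is not stated in the labels, and no biological explanation was tested.

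RNA of 6 T cell genes was found among monocytes and macrophages of the treated libraries. At least 97.556% of it lay in cells with 3 or more of the genes, which were 7.63 to 9.80% of the class, so doublets of a myeloid and a T cell may be its source. Free RNA is argued against, because the cells without any such UMI were at least 6.139 times as frequent as free RNA spread by depth would leave. A first test of free RNA, set before its result, compared the 6 genes with conventional dendritic cells of the same library (3.47-fold in PBS+ICB, 3.69-fold in CTX+IgG and 1.24-fold in CTX+ICB) and left the matter open, so it was replaced by the present one. Doublets were first read in CTX+IgG alone, and the lowest of 3 libraries was taken after the values were seen. Myeloid cells with T cells bound to them were not tested apart from doublets.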

How the results depend on the processing

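Removal of the highest Scrublet scores, of cells with markers of another class and of neutrophils with Elane or Mpo UMIs was chosen after seeing the data. No paired analysis was possible because each treatment had 1 library and the labels match no pools between libraries. The log2 ratios of the CD8 T cell share, in the order of the 5 comparisons of the report, kept their direction under each alternative run. With cells that had an antibody barcode they were 1.07, 0.56, 1.76, 1.203 and 0.69, and with the per-cell gate 1.39, 0.82, 2.07, 1.25 and 0.68. Without the highest Scrublet scores the last 3 were 2.33, 1.27 and 0.685, and the stricter filter gave 1.37 for the fourth. Leaving out the tagged cells of 1 pool gave 1.52 to 1.998, 0.80 to 1.36, 2.49 to 2.86, 1.44 to 1.75 and 0.72 to 1.02. Untagged cells of that pool stayed in, and only 682 of 2220 cells in PBS+IgG and 1999 of 6794 in CTX+IgG were tagged. Among tagged cells of CTX+IgG, CD8 T cells were 63.5% of pool 2 and 12.3 to 29.0% of the other pools. The second ratio can therefore depend on pool 2 more than its range shows. The cause was not tested for these moves, nor for the further moves and reversals that follow. In the first comparison the neutrophil share was 0.36 with antibody barcodes, MHC class II genes of CD8 T cells 0.06 with the gate, and Cxcl2 in CD8 T cells -5.25 to 0.41 without 1 pool. In the second, for CD8 T cells, TMM gave 0.24 for the exhaustion list and 0.08 for the cell cycle, a minimum of 200 UMIs gave 0.023 for naive and memory genes, and Cxcl2 was -4.76 to 1.44 without 1 pool. There, Tox in monocytes and macrophages was -0.154 to 1.77 without 1 pool. In the third, the stricter filter gave 0.026 for cytotoxic genes and the gate -0.15 for the exhaustion list of CD8 T cells. In the fourth, naive and memory genes of CD8 T cells were -0.029 with the gate. In monocytes and macrophages the cell cycle list was 0.45 without the highest Scrublet scores and -0.83 to 1.01 without 1 pool, suppressive genes -0.71 to 0.26 without 1 pool, and Gzmb -2.11 without cells with markers of another class. In the fifth, naive and memory genes of CD8 T cells were -0.016 at resolution 0.5 and -0.53 with the gate, p53 targets -0.049 to 0.29 and Gzmb -0.22 to 0.28 without 1 pool, and Treg activation 0.012 without the highest Scrublet scores. In monocytes and macrophages cytotoxic genes were -0.068 without cells with markers of another class, -0.11 at 200 UMIs and -0.048 to 0.42 without 1 pool, suppressive genes -0.52 to 0.18 without 1 pool, and the cell cycle -1.31 at resolution 2. Among antibodies on CD8 T cells, the CLR gave 0.019 for CD4 in the second comparison and 0.27 for the TCR beta chain in the fifth, and isotype scaling gave -0.037 for CD152 in the second. On monocytes and macrophages isotype scaling gave -0.24 for CD279 in the second comparison, and the CLR gave 0.029 for CD279 and 0.115 for CD152 in the fifth. Of the other values, 255 for shares, 1764 for lists, 867 for genes and 130 for antibodies kept their direction, 4, 123, 18 and 2 changed sign where the reported value was within counting error of 0 or, for lists, within the central 95% of random lists, and of the Trbv numbers 9 stayed within the draws and 3 moved. Among those that changed sign and left the interval were, in the last comparison, the CD4 T cell share (-0.056 with antibody barcodes) and the Treg share (-0.25 without CTX+ICB pool 2), and in the second comparison the Treg share (0.098 without PBS+IgG pool 5). For MHC class II genes of CD8 T cells in the second it was -1.215 without CTX+IgG pool 1, and for monocytes and macrophages the cell cycle list was 0.56 with antibody barcodes there. Genes of this class in the fourth were Pdcd1 (1.23) and Ifng (1.44) without CTX+IgG pool 1 and Mki67 (-0.55) without CTX+ICB pool 4. Depth limits the classes with few cells, since neutrophils of CTX+ICB numbered 50 and CD4 T cells of PBS+IgG 79, and lists with too few measured members have no median.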

Other observations

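Tests of hypotheses are given above, and the values here carry none. Classes outside the compared ones also differed in share. B cells, the antibody-producing lineage, were 6.71% of PBS+IgG, 2.60% of PBS+ICB, 0.618% of CTX+IgG and 0.525% of CTX+ICB. Conventional dendritic cells, which present antigen to T cells, were 4.14%, 2.11%, 5.15% and 1.01%, and mature dendritic cells with Ccl22, Fscn1 and Il12b among their leading genes 1.44%, 0.366%, 1.41% and 0.343%. Plasmacytoid dendritic cells, marked by Siglech, were 0.991%, 0.583%, 1.85% and 0.228%, and basophils or mast cells, marked by Fcer1a and Cpa3, 0.135%, 0.150%, 0.677% and 0.525%. Gzma in NK cells was at 5271 CPM in PBS+IgG, 11855 in PBS+ICB, 8011 in CTX+IgG and 10445 in CTX+ICB. Whether RNA of NK cells adds to the Gzma values of CD8 T cells was not tested. NK cells lay mostly in cluster 1 (77.2%, 57.1%, 78.9% and 72.1%), with 10.7%, 35.5%, 10.8% and 19.5% in cluster 15, which carries Cma1, S1pr5 and Gzma.

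The melanoma gene Mlana was at 21.1, 3.69, 3.24 and 1.09 CPM in monocytes and macrophages. The 4 T cell receptor libraries have no deposited processed file and were not analysed here.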
